A study of Macaca mulatta with 38 samples.

How the data were processed

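Barcodes carried by a lentiviral library were counted in DNA of blood cells from 1 rhesus macaque, a male of 4 years named ZL34. Per the labels' protocols, its mobilised CD34+ cells were transduced at a multiplicity of infection of 25 and given back after TBI, and the animal received cidofovir at 5 mg/kg each week. Barcodes were amplified from 200 ng of DNA over 28 PCR cycles, per the labels' protocols. The sequencer, the program that read the barcodes and the rules by which reads were merged or dropped are not given in the sources used here.

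The authors deposited 1 table of read counts, with 44423 sequences of 50 bases as lines and the 38 libraries as columns. The unit was taken from the values, which are whole numbers with a different sum in each column, since no header states it. The smallest count above 0 was 101 in the table and at most 117 in any library, so a 0 was taken as 100 reads or fewer. This limit is inferred, since the rule is not given in the sources used here, and under another rule for dropping counts the bounds on folds and shares would not hold. A column sum is therefore the reads of the kept barcodes and not the whole depth of the library. It ran from 766039 to 3832849 reads, and was smallest in the T and B libraries of day 494, at 766039 and 789584. 43749 sequences began with GCAACT, 671 with GGCAAC and 3 with AACTCC. The start of a sequencing adapter, AGATCGGAAGAGC, lay within 43259 of them, after 33 bases in 35201, so the variable part is shorter than the 50 bases. 17715 sequences (39.9%) had counts in 1 library only. No sequence was trimmed, merged or removed here. Genomic integration sites were not analysed here.

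Each library was named by the cell type and the day in its labels. Barcodes were numbered bc1, bc2 and so on by mean percent of reads over the 38 libraries. Groups of barcodes that rose and fell together were found among the 51 barcodes that reached 1% of reads in some library. Pearson's r was taken over the 38 libraries on log2(percent + 0.01), and complete linkage joined barcodes only where every pair in a group had r of at least 0.95. The same steps were run on 100 tables in which the days of each barcode were shuffled within each lineage. The group with the highest mean share in the nRBC libraries was called the leading group, here group 1. Diversity was the effective number of barcodes, the exponential of the Shannon entropy of the read shares.

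Trends over days were tested by Spearman's rho and Pearson's r with two-sided exact permutation p-values, and lineages by the mean difference over the 7 days shared by T, B, Gr and Mono with a two-sided exact sign-flip permutation test. Benjamini-Hochberg adjustment covered the 4 trends or the 3 lineage comparisons of each measure. Single barcodes were tested with edgeR's quasi-likelihood test on the deposited counts, over barcodes with at least 0.05% of reads in at least 2 libraries of the fit. Scaling was by the column sums, since TMM assumes that most features do not change. Lineage fits held day as a block, and slope fits gave each lineage its own intercept and its own slope per 100 days. A barcode was called at an adjusted p under 0.05. Its standard error was the log2 change over the square root of the F statistic. Similarity of libraries was Pearson's r over barcodes of the square root of the read share. Barcodes are not independent replicates in it, so it was not tested. Shares of single libraries have exact Clopper-Pearson intervals at 95%, which cover counting error only, since PCR reads without molecular identifiers are not independent molecules.

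The libraries of a lineage are serial samples of 1 animal and not biological replicates. A permutation p-value here says only how unlike a random order, or a random swap of lineages within days, the values of this animal were. An edgeR p-value instead takes the libraries as independent samples, which serial days of 1 animal are not, so it measures neither. The day was the matched unit. No batch, run or lane is given in the labels, so none was tested, and no 2 libraries held identical values.

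The barcodes named in the text were chosen by a rule. It took every member of a group, or single barcode, whose share reached 5% in some library, up to 12 members, and the 5 barcodes with the highest mean share in each of T, B, Gr, Mono and nRBC and in the EOS and CD34p libraries. It also took, for each edgeR comparison, the 3 called barcodes with the largest change in each direction that held at least 0.5% of reads in some library of the fit. The groups, tests, alternatives and this rule were set before the data were examined, except where the text says otherwise.

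The alternatives were TMM factors, DESeq2 with size factors from positive counts, barcode filters at 0.01% and none, no day block, log2 of day, the inverse Simpson index, thinning each library to 766039 reads, r of 0.90 and 0.98 within groups, pseudocounts of 0.001 and 0.1, and leaving out each day in turn. A setting with each 0 at 100 reads and one with bc11 counted in group 1 were chosen after seeing the data.

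The edgeR step was tested on simulated data with counts of 100 or fewer set to 0. For T against Gr, with 379 barcodes and a dispersion of 0.2, it recovered 126 of 126 barcodes changed 8-fold. For nRBC against T, with 138 barcodes, it recovered 35 of 46, and 7.89% of its calls were wrong. With the dispersions estimated from the data, whose medians were 6.72 and 4.11, it recovered 0 of 126 and 0 of 46, both for 8-fold and for 64-fold changes. For slopes in Gr, with 415 barcodes, it recovered 138 of 138 changed 8-fold at a dispersion of 0.2 and 0 of 138 at the estimated dispersions, where it recovered 35 of 138 changed 64-fold. For nRBC against Gr, with 7 barcodes, it recovered 1 of 2 changed 8-fold at either dispersion. A low number of calls is therefore weak evidence of little change. The grouping step was tested on simulated data too, and found 140 of 140 simulated clones exactly, at an SD of 0.3 for the log2 deviation of each member from its clone. Each simulated clone had its own random order of libraries, and low counts were not set to 0. The test therefore does not show that clones with a shared time course are told apart. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0 were used.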

Results

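Clonal output of transplanted blood stem and progenitor cells was followed in 1 rhesus macaque by counting lentiviral barcodes in 38 libraries of sorted blood cells. A barcode is a short DNA tag that the vector inserts into a cell's genome and that all descendants of the cell inherit. The read share of a barcode therefore tracks the share of its descendants' DNA among barcoded cells. The labels name 9 libraries T, 8 B, 7 Gr, 7 Mono, 5 nRBC, 1 EOS and 1 CD34p, all from peripheral blood, at days 32 to 553. T, B, Gr and Mono share 7 days. The nRBC libraries begin at day 266. Reads of kept barcodes per library ran from 766039 to 3464834 in T, 789584 to 3365960 in B, 1438491 to 3805440 in Gr, 1922035 to 3786747 in Mono and 3536732 to 3832849 in nRBC. The EOS library had 3768274 and the CD34p library 3776590. Each lineage and day has 1 library from 1 animal, so there are no biological replicates, and the spreads below are over days. No count from 1 to 100 occurs, so a listed 0 is taken here as 100 reads or fewer, which is at most 0.0131% of a library, in the T library of day 494. This limit is inferred from the counts, and all bounds below rest on it.

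The most abundant barcodes fell into groups that rose and fell together across lineages and days. A cell with several vector copies carries several barcodes, but clones with the same time course would group as well. 51 barcodes reached 1% of reads in some library. 49 of them belonged to 8 groups of 3 to 11 members, and 2, bc11 and bc87, stood alone. 272 of the 1275 pairs had r of at least 0.95, against a median of 0 and a highest value of 2 in 100 tables with the days shuffled within each lineage. The largest group in the shuffled tables had 2 members. The shuffling removes any time course that barcodes share, so it does not show that the members of a group sat in 1 cell.

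Group 1, the leading group, held 6 barcodes, bc1 to bc6, and they made up nearly all reads of every nRBC library. Their lowest pairwise r was 0.993, and the log2 ratio of a member to the largest had a median SD of 0.22 over libraries. In the 5 nRBC libraries bc1 (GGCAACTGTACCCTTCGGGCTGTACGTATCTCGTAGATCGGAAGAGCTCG) held 19.1% ± 2.08 of reads (SD, n = 5 days) and bc2 (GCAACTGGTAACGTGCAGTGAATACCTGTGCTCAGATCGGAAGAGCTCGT) 18.4% ± 1.41. bc3 (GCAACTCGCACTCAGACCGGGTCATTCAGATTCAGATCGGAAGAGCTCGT) held 16.3% ± 1.62 and bc4 (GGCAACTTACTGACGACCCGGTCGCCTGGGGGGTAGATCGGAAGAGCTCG) 15.7% ± 1.95. bc5 (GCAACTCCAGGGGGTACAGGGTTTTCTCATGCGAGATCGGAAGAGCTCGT) held 14.4% ± 1.26 and bc6 (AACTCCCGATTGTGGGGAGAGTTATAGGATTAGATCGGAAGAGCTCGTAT) 14.3% ± 3.73. The 6 barcodes formed the leading group under each other pseudocount, threshold on r and minimum share tried. With percentages that were not logged, 5 of them did.

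The group 1 share rose with time in all 4 lineages followed from day 32. It was 91.7% in Mono and in Gr at day 365 and higher after that, and at most 48.9% in T and 41.4% in B. In Mono it was 0.256% at day 32, 0.952% at day 119, 14.6% at day 187, 41.1% at day 266, 91.7% at day 365, 99.9% at day 494 and 99.8% at day 553. In Gr it was 0.143%, 2.90%, 0.960%, 15.6%, 91.7%, 94.1% and 99.8% on the same days. In T it was listed at 0 at day 32, where the counts allow up to 0.0349%. It was 0.413% at day 119, 0.616% at day 187, 5.40% at day 266, 14.4% at day 365, 2.92% at day 393, 3.98% at day 494, 13.1% at day 536 and 48.9% at day 553. In B it was 0.0152% at day 32 with 3 of the 6 members listed, 0.171% at day 119, 0.415% at day 187, 10.6% at day 266, 7.24% at day 365, 3.44% at day 393, 5.29% at day 494 and 41.4% at day 553. The exact 95% interval of the last share was 48.9 to 49.0% in T and 41.3 to 41.4% in B, for counting error only.

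**Figure D1:**
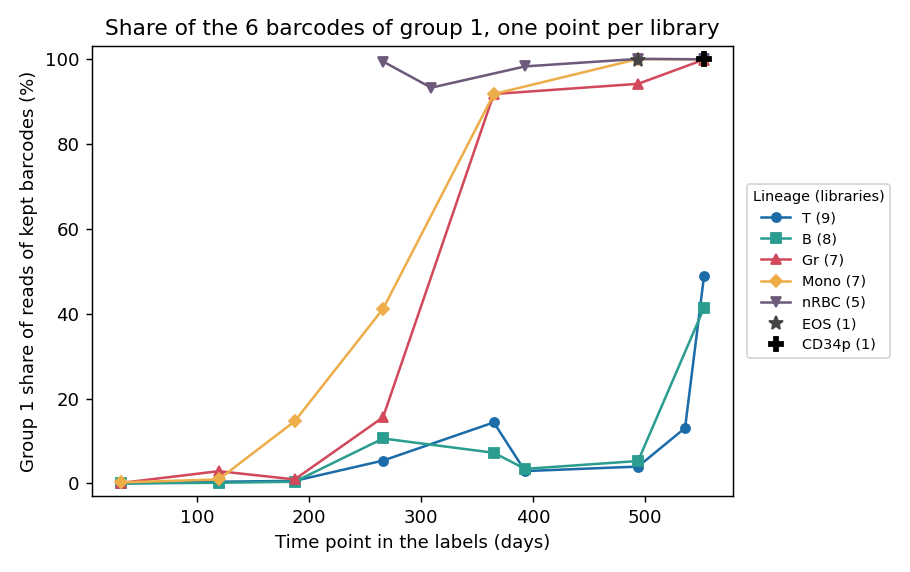
Group 1 share of the reads of kept barcodes in percent (vertical axis) against the time point in days (horizontal axis), 1 point per library and 1 line per lineage. Gr and Mono lie at 91.7% from day 365 or above, nRBC at 93.2% or above throughout, and T and B at 48.9% and 41.4% at most.

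Against day, the group 1 share had Spearman's rho of 0.964 in Mono (exact permutation p = 0.00278, adjusted p = 0.00556, n = 7) and the same values in Gr. Pearson's r was 0.958 in Mono (exact permutation p = 0.000397, adjusted p = 0.00119) and 0.923 in Gr (exact permutation p = 0.000595, adjusted p = 0.00119). In T rho was 0.817 (exact permutation p = 0.0108, adjusted p = 0.0144, n = 9) and r 0.629 (exact permutation p = 0.0347, adjusted p = 0.0347). In B rho was 0.786 (exact permutation p = 0.0279, adjusted p = 0.0279, n = 8) and r 0.669 (exact permutation p = 0.031, adjusted p = 0.0347). Each adjustment covered 4 lineages. Without the 2 days farthest from the median day, r was 0.967 in Mono, 0.917 in Gr, 0.598 in T and 0.451 in B. The rise in T and in B no longer passed the threshold without day 32, 119, 187 or 553, with rho down to 0.738 in T and 0.679 in B. Matched by day, the share was lower in T than in Gr by a mean of −33.1 percentage points (SD 39.0, n = 7 days, exact permutation p = 0.0156, adjusted p = 0.0234), with 7 of 7 days lower. In B it differed from Gr by −34.3 points (SD 41.3, exact permutation p = 0.0156, adjusted p = 0.0234, n = 7), also with 7 of 7 days lower. In Mono it differed by 6.18 points (SD 10.1, exact permutation p = 0.156, adjusted p = 0.156, n = 7), higher on 5 of 7 days. The smallest p that 7 days allow is 0.0156. Counted over barcodes with at least 0.05% of a library's reads only, the difference was −13.1 points in B with exact permutation p = 0.406 with adjusted p = 0.406, and −32.2 points in T with exact permutation p = 0.0312 and adjusted p = 0.0938, so neither passed. These are shares of the reads of those barcodes and not of the whole library. They are therefore another measure than the differences above.

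Diversity fell with time in B, Gr and Mono, to about as many barcodes as group 1 has in Gr and Mono. The effective number of barcodes in Gr was 8050 at day 32, 82.1 at day 119, 1185 at day 187, 1423 at day 266, 7.06 at day 365, 6.77 at day 494 and 6.01 at day 553. In Mono it was 8846, 49.7, 145, 145, 7.65, 6.01 and 6.03. In B it was 14375 at day 32, 6523 at day 119, 9992 at day 187, 4573 at day 266, 4643 at day 365, 7370 at day 393, 2405 at day 494 and 700 at day 553. In T it was 479 at day 32, 1375 at day 119, 348 at day 187, 502 at day 266, 455 at day 365, 780 at day 393, 153 at day 494, 393 at day 536 and 129 at day 553, and in nRBC 5.99 to 6.89. The number of barcodes listed ran from 12 to 10210 in Mono, from 18 to 8820 in Gr, from 3296 to 15815 in B and from 525 to 8450 in T. A 0 could hide up to 0.0127% of reads in B and 0.0131% in T at day 494, against 0.0032% in each at day 393. How far this lowered the diversity listed at day 494 was not tested, since thinning started from counts that were already cut.

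**Figure D2:**
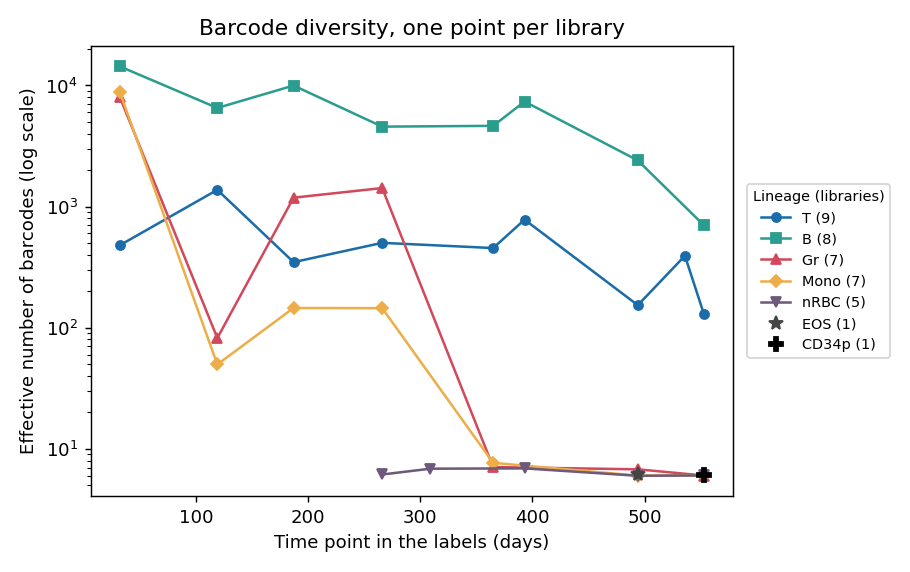
Effective number of barcodes (vertical axis, log scale) against the time point in days (horizontal axis), 1 point per library and 1 line per lineage. Gr and Mono lie at 7.06 and 7.65 or below from day 365, and B at 700 or above throughout.

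Against day, the effective number had Spearman's rho of −0.857 in Gr and in Mono (exact permutation p = 0.0238, adjusted p = 0.0372, n = 7 each), −0.786 in B (exact permutation p = 0.0279, adjusted p = 0.0372, n = 8) and −0.600 in T (exact permutation p = 0.0968, adjusted p = 0.0968, n = 9). Pearson's r was −0.654 in Gr (exact permutation p = 0.051, adjusted p = 0.102), −0.595 in Mono (exact permutation p = 0.146, adjusted p = 0.146), −0.854 in B (exact permutation p = 0.00565, adjusted p = 0.0226) and −0.533 in T (exact permutation p = 0.132, adjusted p = 0.146). Without the 2 days farthest from the median day r was −0.380 in Gr, −0.573 in Mono, −0.627 in B and −0.395 in T, so the trends in Gr and B rested in part on those days. The trends in Gr, Mono and B each lost the threshold without day 32, 187, 365, 494 or 553, with rho no weaker than −0.771 in Gr and Mono and −0.679 in B. Over barcodes with at least 0.05% of reads, rho was 0.405 in B and −0.643 in Gr. At day 32 this filter cut the effective number in B from 14375 to 1. The positive rho in B therefore does not show that diversity rose there. With the groups summed into 1 clone each, the fall in T passed (rho −0.817). Matched by day, B was more diverse than Gr by a mean log2 ratio of 5.23 (SD 3.36, exact permutation p = 0.0156, adjusted p = 0.0469), on 7 of 7 days. T differed from Gr by 1.67 (SD 3.98, exact permutation p = 0.297, adjusted p = 0.297), higher on 4 of 7 days, and Mono by −0.99 (SD 1.51, exact permutation p = 0.156, adjusted p = 0.234), lower on 4 of 7 days. Without any 1 of the days the difference of B did not pass (exact permutation p = 0.0312, adjusted p = 0.0938, the smallest value that 6 days allow). Over barcodes with at least 0.05% of reads the mean log2 ratio of B to Gr was 0.13 with exact permutation p = 0.922. That filter left an effective number of 1 in B and 23.4 in Gr at day 32, so this ratio leaves out the rarer barcodes.

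Groups 2, 3, 5 and 6 had their highest shares in Gr, Mono and T at day 119 or 187, and by days 494 and 553 held at most 0.0239% of Gr and Mono reads, when T still listed all their members. Group 2, bc7 to bc10, held 34.6% of Gr reads at day 119 and 31.2% of Mono reads at day 187, and 0.0239% and 0.0103% at day 553. In T it held 25.9% at day 187 and 6.73% at day 553, and in B at most 1.95%. Group 3 (11 barcodes from bc12 to bc46) held 24.8% in Mono, 16.3% in Gr, 9.23% in T and 3.05% in B at day 119, and 2.95% in T at day 553. Group 5 (9 barcodes from bc32 to bc44) held 24.7% in Mono, 14.8% in Gr and 4.56% in T at day 119, and 1.04% in T at day 553. All members of groups 3, 5 and 6 were listed at 0 in Gr and Mono at days 494 and 553. Group 6, bc25, bc26, bc30 and bc36, was highest at 8.51% in Mono at day 187. bc11, which stood alone, reached 7.95% in Gr at day 365, 6.47% in Mono at day 365, 6.09% in nRBC at day 309, 1.03% in T and 1.09% in B. These are single libraries with no test.

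**Figure D3:**
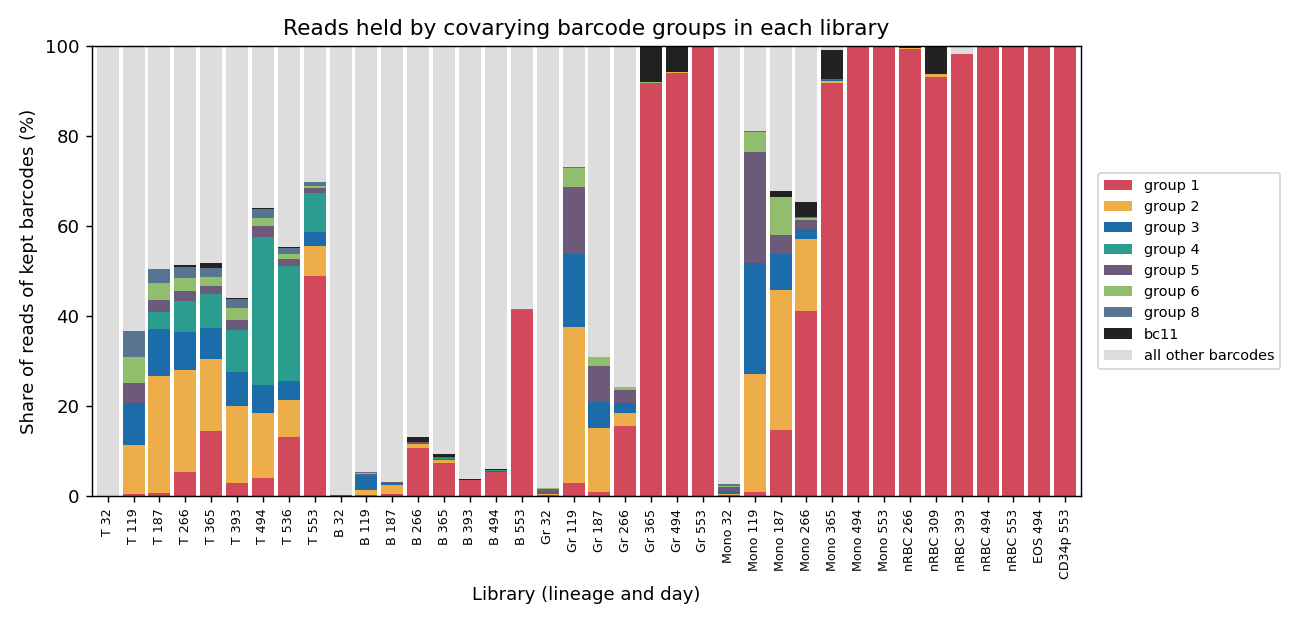
Share of the reads of kept barcodes in percent (vertical axis) held by groups 1 to 6, group 8, bc11 and all other barcodes in each library (horizontal axis, lineage and day), as stacked bars. Group 4 stands out in T, with 32.9% at day 494, and the other barcodes hold most reads of B on each day.

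Group 4 from day 187 and group 8 from day 119 held their highest shares in T. Group 4 (bc13, bc15, bc18, bc19, bc21, bc23 and bc28) held 0.0168% of T reads at day 119, 3.94% at day 187, 32.9% at day 494, 25.7% at day 536 and 8.74% at day 553. At day 32 it was listed in B (0.0206%, 3 of 7 members) and Gr (0.0122%, 1 of 7) and at 0 in T. Its highest share was 0.133% in B, 0.0940% in Mono, 0.0892% in EOS, 0.0389% in Gr and 0.0265% in nRBC. Group 8 (bc47, bc48, bc50, bc51 and bc52) was first seen outside T. At day 32 it held 0.594% of Mono and 0.168% of Gr reads with 5 of 5 members each, and was listed at 0 in T. This is not particular to groups 4 and 8. Groups 1 to 6 were all at 0 in T of day 32, which listed 525 barcodes, and all had reads in Gr of day 32, which listed 8820. Group 8 held 5.98% of T reads at day 119 and 0.833% at day 553, against at most 0.324% in Mono, 0.256% in Gr and 0.132% in B from day 119. In T against Gr, 7 of 7 members of group 4 and 4 of 5 of group 8 were higher by edgeR, with adjusted p between 0.00564 and 0.0404 in group 4. Members of a group were joined by their covariation over these same libraries, so their calls do not add up as separate support. bc19 held 1.25% ± 1.84 in T and 0.00189% ± 0.00329 in Gr (SD, n = 7 days), at least 258-fold higher in T (adjusted p = 0.00564), and at least 111-fold without day 494, where its T mean was 0.576%. bc50 held 0.461% ± 0.402 and 0.0156% ± 0.0256, at least 26.6-fold higher (adjusted p = 0.0198), or 49.1-fold without day 32. bc58 reached at most 0.536% of reads, under the 1% needed to enter the grouping. It held 0.294% ± 0.224 in T and was listed at 0 in 7 of 7 Gr libraries, at least 78.9-fold higher (adjusted p = 0.00213 by edgeR). The bounds set each 0 to 100 reads. Leaving out 1 day left 5 to 7 members of group 4 called, and 0 of 5 members of group 8 without day 187 or 2 without day 266 or 494. bc50 did not pass without day 119, 187 or 266 (adjusted p = 0.0569, 0.0573 and 0.062).

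Of 379 barcodes tested over the 7 shared days, edgeR called 64 higher and 11 lower in T than in Gr. Of the 64, 28 were listed at 0 in all Gr libraries, and 63 had the higher mean share in T. Of the 11, 10 were listed at 0 in all T libraries, and the lower calls were few or many by setting: 5 with TMM factors, 40 by DESeq2, 2 without day 119, 0 without day 187, 1 without day 266, 5 without day 494 and 17 without day 32. None of the 6 members of group 1 passed in T against Gr (log2 −3.15 to −2.56, adjusted p 0.0638 to 0.154). The count of 75 was 45 without day 119 and 37 without day 494, and 47 without the day block, where 0 of 5 members of group 8 passed. With the filter at 0.01% it was 0 and with all barcodes 4, with none of group 4 or group 8 among them. With each 0 at 100 reads it was 139, and DESeq2 called 186. In B against Gr, edgeR called 6 higher and 1 lower, of which 4 and 1 were listed at 0 throughout the other lineage. Named after their values were seen, the highest of the 6 were bc112 (0.0638% in B) and bc170 (0.0525% in B). That count of 7 was 0 without day 119, 365 or 494, 4 without day 187, 4 with TMM factors (4 higher and 0 lower), 46 with each 0 at 100 reads, 456 with the filter at 0.01%, 0 with all barcodes and 146 by DESeq2. In Mono against Gr edgeR called 0 barcodes, with 21 at an unadjusted p under 0.05, and DESeq2 called 33.

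The nRBC libraries were set against T and Gr of the same days. Group 1 held 99.3%, 93.2%, 98.2%, 99.9% and 99.9% of nRBC reads at days 266, 309, 393, 494 and 553. At day 266 its share was 15.6% in Gr and 41.1% in Mono. Over 4 shared days bc1 held 19.9% ± 1.20 in nRBC and 2.92% ± 4.33 in T (SD, n = 4 days), a log2 change of 4.01 ± 1.26 (SE, adjusted p = 0.00192 by edgeR). bc5 changed by 3.95 ± 1.46 (adjusted p = 0.00726) and bc6 by 3.94 ± 1.38 (adjusted p = 0.00478). bc24 was listed at 0 in all 4 nRBC libraries and held 0.930% ± 0.364 in T, at least 352-fold lower in nRBC (adjusted p = 0.00246). The bound was 334-fold for bc12 and 313-fold for bc14. Of 138 barcodes tested, the 6 of group 1 were higher and 131 were lower, all members of groups 2 to 8 among them. Of the 131, 114 were listed at 0 in nRBC, so they passed the filter through T only. Group 1 was chosen by its share in these nRBC libraries, and shares in a library sum to a fixed total. The direction of these calls was therefore largely set in advance. The size of the change in group 1 depended on the setting. The log2 changes of its members were 3.72 to 4.01 as reported, 4.71 to 5.02 with TMM factors, 8.77 to 9.08 by DESeq2, 2.49 to 3.03 without the day block and 4.50 to 4.79 without day 553. The ratio of the mean shares of bc1 was 6.82, and 26.6 without day 553. The 6 did not pass with TMM factors (adjusted p 0.0960 to 0.117), with all barcodes or without day 266, 1 passed without day 393, and 3 without day 494 or without the day block. The whole count was 137, and 78 without day 553, where bc24, bc12 and bc14 did not pass (adjusted p = 0.0876, 0.0975 and 0.1). With the filter at 0.01% it was 467 and with all barcodes 2382. Against Gr over 3 days, 0 of 7 barcodes were called by edgeR, with 0 at an unadjusted p under 0.05, and DESeq2 called 1. The similarity r of nRBC, taken over barcodes on each matched day and averaged over days, was 0.891 ± 0.189 to Mono (SD, n = 3 days), 0.796 ± 0.331 to Gr (n = 3), 0.372 ± 0.211 to B and 0.339 ± 0.246 to T (n = 4 each). With Gr it was 0.415 at day 266 and 0.999 at day 553. With shares that were not transformed, the r of nRBC and B was 0.847, and without group 1 it was 0.0908.

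Single barcodes that rose or fell over days were called in Gr and Mono and not in T or B, out of 415 tested. In Gr, 2 had a positive slope and 12 a negative one. bc11 had a log2 slope of 5.64 ± 1.79 per 100 days (SE, adjusted p = 0.0467), but its Gr shares were not a steady rise: 0 at days 32, 119 and 187, 0.0738% at day 266, 7.95% at day 365, 5.86% at day 494 and 0.151% at day 553. bc18 of group 4 had a slope of 2.75 ± 0.85 (adjusted p = 0.0467). With each 0 at 100 reads the slope was 2.57 for bc11 and −0.08 for bc18. bc68, bc72 and bc75 had slopes of −4.24 ± 1.32, −4.21 ± 1.32 and −4.16 ± 1.30 (adjusted p = 0.0467 each), and −1.69, −1.65 and −1.61 with each 0 at 100 reads. In Mono 21 fell, with bc84 at −3.89 ± 1.26 (adjusted p = 0.041), or −1.28 with each 0 at 100 reads. The members of group 1 had slopes of 1.66 to 1.84 in Gr and did not pass (adjusted p 0.113 to 0.137). edgeR called 0 slopes in T, with 35 at an unadjusted p under 0.05, and 0 in B, with 24, while DESeq2 called 56 and 50. The counts were unstable. In Gr the count was 0 without day 119, 187, 365, 393, 494 or 553, 1 without day 536, 236 without day 266 and 316 without day 32. In Mono it was 0 without day 119, 187, 365, 494 or 553, 12 without day 393, 33 without day 266 and 205 without day 32. Gr and Mono have no library of day 393 or 536. Leaving out these days removed only T or B libraries from the shared fit, so the counts in Gr and Mono depended on those too. Without day 32 it was 5 in T and 16 in B, and without day 536 it was 1 in T. TMM factors gave 39 in Gr, 1 rising and 38 falling, and 69 in Mono, and DESeq2 gave 377 and 338. The slope differed between T and Gr for 2 barcodes, bc125 and bc271, named after their values were seen, and this count was 277 without day 32, 229 without day 266 and 0 without any 1 of the other days. It differed from Gr for 0 barcodes in B and 0 in Mono by edgeR, with 36 and 1 at an unadjusted p under 0.05, while DESeq2 called 324 and 44. For B it was 233 without day 32.

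The single EOS and CD34p libraries resembled nRBC and Mono of their days. Group 1 held 99.7% of EOS reads at day 494 (exact 95% interval 99.66 to 99.67%) and 99.9% of CD34p reads at day 553 (99.85%, both bounds). The similarity r of EOS was 0.999 to nRBC and to Mono, 0.975 to Gr, 0.239 to B and 0.236 to T. For CD34p it was above 0.999 to nRBC, Mono and Gr, 0.706 to T and 0.674 to B. The effective number of barcodes was 6.14 in EOS and 6.02 in CD34p, with 36 and 12 barcodes listed. With 1 library each there is no test. CD34p is labelled as peripheral blood.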

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

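All tests in this part except the search for libraries far from the others and the tests of slope differences were chosen, or their outcomes set down, after the results were seen.

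A library lay far from the others of its lineage in 7 of the 20 sets of values searched. The rule flags about 1 in 20 sets of independent, normally distributed values. These sets are skewed and tied to each other, so that rate does not hold for them. The group 1 share at day 553 was 48.9% in T, with the next highest at 14.4%, and 41.4% in B, with the next at 10.6%. The effective number of barcodes at day 32 was 8050 in Gr, with the next at 1423, and 8846 in Mono, with the next at 145. The cut of low counts bears on these day 32 values, to an extent that was not tested. The Mono library of day 32 also listed 10210 barcodes, with the next at 3670. Among the nRBC libraries, that of day 309 had the lowest group 1 share, 93.2%, and that of day 393 listed 201 barcodes, with the next at 30. These sets hold ordered days, so the first and last days can stand apart through a trend. By the edgeR test of the difference, 2 barcodes had a higher log2 slope per 100 days in T than in Gr, bc125 by 4.92 ± 1.26 (SE, adjusted p = 0.0403) and bc271 by 4.44 ± 1.20 (adjusted p = 0.046).

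bc11 followed group 1 in some libraries and lay far below it in others, with a ratio of bc11 to group 1 between 0.000464 and 0.114 over the 29 libraries that list it. At day 266 the ratio was 0.0822 in Mono, 0.0817 in T and 0.103 in B, and 0.00474 in Gr and 0.00486 in nRBC. One candidate explanation is that the recovery of single barcodes differed between libraries, and then an unrelated ratio, that of bc10 to the mean of bc7, bc8 and bc9, would be low in the same ones: over 25 libraries, 7 of them with bc11 at 0 and set to 100 reads, rho was 0.562 (permutation p = 0.00422, adjusted p = 0.0136) and r 0.563 (permutation p = 0.0068, adjusted p = 0.0136, 0.667 without the 2 farthest libraries). Over the 18 libraries that list bc11, rho was 0.265 (permutation p = 0.285, adjusted p = 0.285) and r 0.496 (permutation p = 0.0645, adjusted p = 0.086, 0.512 without the 2 farthest), with 4 tests in the family. The 7 libraries left out had bc10 ratios of 0.127 to 0.403, so leaving them out narrowed the range of that ratio and can weaken rho. Over the 9 libraries of days 187 and 266, among them Gr of day 187 with bc11 at 0, rho was 0.817, with no test. This explanation stays open. A separate clone with bc11 stays open too: within a lineage, the median step of the ratio between neighbouring days was 1.18 in absolute log2 over 22 steps, which neither needs nor forbids one.

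Group 1 in the T and B libraries may come from its descent into these lineages or from DNA of other cells in the sorted samples. At day 266, DNA from Gr cells would bring the other Gr barcodes too, but 92.6% of the 54 barcodes with at least 0.1% in Gr lay below 0.5 times the share they would need in B, and 24.1% in T. For DNA from Mono cells it was 80% of 30 barcodes in B, which argues against Mono cells as the only source, and 0% in T, where DNA from Mono cells stays open. The share needed assumes that 1 source brought all of group 1. A part from Gr or Mono cells, or a mix of sources, was not tested. DNA from nRBC, or other cells with little but group 1, cannot be told apart from descent, since nRBC offers only 1 usable barcode outside group 1 for T and 1 for B. Descent of T and B cells from group 1 was not tested, and at day 553 Gr and Mono hold too little else for this test.

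Group 1 at days 32 and 119 may be early output or carry-over of reads from the later libraries. Carry-over in proportion to all reads would bring group 4 along at the pooled ratio of group 1 to group 4, and in Gr of day 119 the ratio was at least 4.62 times the pooled one, which argues against it there. Where group 4 was listed, the ratio was between 0.564 and 1.02 times the pooled one in T and 0.140 and 0.2 in B at day 119, and 0.110 and 0.485 in Gr and 0.0174 and 0.0307 in B at day 32, within what carry-over allows, so it stays open in these 4 libraries. In Mono, at least 1.48 times at day 119 and 0.293 at day 32, group 4 was at 0 and nothing is decided. Carry-over from 1 library rich in group 1, such as nRBC, was not tested.

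Lineage labels were swapped within days to see how often other splits call as many barcodes. For T against Gr, 2 of 64 splits called as many as the real 75, with 83 in the highest other, which swapped day 32. For B against Gr 1 of 64 did, the real one with 7, and the highest other called 2. For the slope difference of T and Gr 1 of 64 did, the real one with 2, and the highest other called 1. Each of these 3 shares was under 5% taken alone, but adjusted over the 8 comparisons they were 0.0833, 0.0625 and 0.0625, so chance was not excluded across them. The splits decide nothing for Mono against Gr, for the slope difference of B and Gr or for that of Mono and Gr, since any split meets a real count of 0 (64 of 64, with 0, 2 and 0 in the highest others). For nRBC against T (real 137, highest other 0, 1 of 8 splits) and against Gr (real 0, highest other 0, 4 of 4 splits), the splits are too few for a share under 5%.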

How the results depend on the processing

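The settings with each 0 at 100 reads and with bc11 in group 1 were chosen after seeing the data. The rise of the group 1 share in Gr and Mono passed under every setting run. Group 1 had 6 members under each setting of the grouping step but percentages that were not logged, which gave 5. The cause of the changes below was not tested, except that leaving out days leaves fewer libraries and that 6 days cannot give a sign-flip p under 0.0312.

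Over barcodes with at least 0.05% of reads, rho of the diversity trend was 0.405 in B, turned in sign, and −0.643 in Gr. The mean log2 ratio of diversity in B to Gr was then 0.13. This filter cut the effective number in B at day 32 from 14375 to 1, so neither value describes all barcodes of B. The group 1 share, taken of the reads of those barcodes only, differed from Gr by −32.2 percentage points in T and −13.1 in B. With groups summed, rho of the diversity trend in T was −0.817. Leaving out 1 day, rho of the diversity trend ran from −0.929 to −0.679 in B and from −0.943 to −0.771 in Gr and in Mono. The mean log2 ratio of diversity in B to Gr ran from 4.54 to 5.96. For the group 1 trend, rho ran from 0.738 to 0.929 in T and from 0.679 to 0.893 in B. The similarity of nRBC and B was 0.847 with untransformed shares and 0.0908 without group 1.

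Calls in T against Gr (75 as reported) were 186 by DESeq2, 0 with the filter at 0.01%, 4 with all barcodes, 47 without the day block, 139 with each 0 at 100 reads, and 37 to 99 leaving out 1 day. Calls in B against Gr (7) were 4 with TMM factors, 146, 456, 0 and 46 by DESeq2, the 0.01% filter, all barcodes and each 0 at 100 reads, and 0 to 9 leaving out 1 day. Calls in Mono against Gr (0) were 33 by DESeq2, and in nRBC against Gr (0) 1. Calls in nRBC against T (137) were 467 with the 0.01% filter, 2382 with all barcodes and 78 to 107 leaving out 1 day.

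With TMM factors, slopes were called for 1 barcode in T, 1 in B, 39 in Gr and 69 in Mono, and the slope difference of T and Gr for 26. By DESeq2 it was 56, 50, 377 and 338, and 366, 324 and 44 for the differences of T, B and Mono. With the 0.01% filter it was 100 in T, 0 in Gr and 1655 in Mono, and 55 for the difference of T. With all barcodes it was 354 in T, 0 in Gr and 0 in Mono. With log2 of day it was 5 in T, 2 in B, 2 in Gr and 1 in Mono, and 0 for the difference of T. With each 0 at 100 reads it was 52 in T, 65 in Gr and 62 in Mono, and 161 and 226 for the differences of T and B, while the slope of bc18 in Gr turned to −0.0839. Leaving out 1 day gave 0 to 5 in T, 0 to 16 in B, 0 to 316 in Gr, 0 to 205 in Mono, and 0 to 277 and 0 to 233 for the differences of T and B.

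Of the other settings for barcodes named from a test, 59 kept the call, 30 kept the direction but missed the threshold and 1 turned in sign, and leaving out 1 day kept 44 calls and ended 51. The scaling moved the median fitted log2 change of all tested barcodes from −0.64 to 0.04 in Mono against Gr, from 3.04 to 4.10 in B, from 3.06 to 3.16 in T, from −14.19 to −13.96 in nRBC against T and from 0.87 to 0.01 in nRBC against Gr with TMM factors. The median slope moved from −3.18 to −3.40 in Gr, from −2.65 to −3.17 in Mono, from 0.36 to 0.20 in T and from 0.36 to 0.11 in B, and the median slope difference from 0.44 to 0.08 for Mono and from 3.54 to 3.42 for B. Barcodes at 0 are bounded only by 100 reads, so fitted changes against them have no firm size.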

Other observations

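The test of read starts in this part was chosen after the values were seen. Most barcodes of day 32 in Gr, Mono and T were not listed again in a later library of their own lineage, unlike those of B. In Gr, 1491 of the 8820 barcodes of day 32 were listed again in a later Gr library, and they held 20.3% of its reads at day 32. In Mono it was 1637 of 10210 barcodes with 20.2% of reads, in T 188 of 525 with 37.3% and in B 7996 of 15815 with 53.7%. Counting any other library, the shares were 86.3% in Gr, 88.4% in Mono, 78.6% in T and 68.9% in B. A barcode not listed again can still have reads below the limit of the table. After day 32 the libraries listed 3296 to 13465 barcodes in B, 1019 to 8450 in T, 18 to 4871 in Gr and 12 to 3670 in Mono. The lineages therefore differ in how many barcodes could be listed again. The Gr and Mono libraries had a similarity r of 0.233 at day 32, 0.934 at day 119, 0.717 at day 187, 0.750 at day 266 and 0.991 at day 365. At day 32 T had 0.0144 to Gr and 0.0119 to Mono.

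Group 4, highest in T, was also listed at low shares elsewhere: all 7 members had reads in B of day 365 (0.133% in sum) and day 393 (0.0570%), in Mono of day 365 (0.0940%), in EOS of day 494 (0.0892%), in Gr of day 553 (0.0364%) and in nRBC of day 393 (0.0265%).

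Read shares count barcode copies and not cells. If every cell of group 1 held 6 barcodes and every other cell 1, the cells of group 1 would make up 13.8% of T and 10.5% of B at day 553, 2.99% of Gr and 10.4% of Mono at day 266, and 96.1% of nRBC at day 266. The number of copies in other cells was not measured here, and groups of 3 to 11 barcodes occur among them.

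3 of the 6 members of group 1 began with another sequence than GCAACT, against 671 of the 44417 other barcodes (1.51%, two-sided Fisher exact p = 6.72e-05). Of the 45 other barcodes that reached 1%, 1 did, bc22 of group 7. No other sequence of the table was equal to any of these 4 after a shift to the usual start. Whether such sequences are barcodes in their own right or shifted or altered reads was otherwise not tested, and this bears on the number of members of group 1.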
